A study of Nephotettix cincticeps with 14 samples.

How the data were processed

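Gene expression was compared between green rice leafhopper females (Nephotettix cincticeps, a sap-feeding insect of rice) pricked with E. coli and females pricked with sterilized water, with 2-colour Agilent oligonucleotide arrays on which the RNA of a challenged pool and of a control pool were labelled with Cy3 and Cy5. Per the labels, each sample pooled 5 females, RNA was taken 3 h or 12 h after pricking, and there were 3 biological replicates at 3 h and 4 at 12 h, each with a dye-swapped array, which made 14 arrays. Nothing in the labels ties a 3 h pool to a 12 h pool.

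The deposited scanner files held raw intensity values, the median brightness of each spot and of its local background in both channels, read with Agilent Feature Extraction. The version was 9.5.3.1 per the file headers and 9.5.1 per the submitters' processing notes. The same files held processed intensity values that were background-subtracted and dye-normalized, per the file headers, and a log10 ratio of Cy5 over Cy3. The authors' series matrix held that log10 ratio rounded, with every column's median at 0 and the swapped arrays not turned. The design fixed before the data were examined named the mean spot signal; the files hold the median signal, which was used in its place.

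Each array held 15744 spots, of which 536 were control spots and 15208 belonged to 15133 probes of the study. Of these probes, 15 had 6 spots each. The IDs named 9180 sequences, most with 2 probes. The spot tables do not pair the IDs with gene names, their 1 column of systematic names differing from the probe ID in 0 of the study's spots, so none of the 32 gene lists fixed before the data were examined could be matched and the gene list tests were not run. The letters at the start of an ID formed 14 groups, and their meaning is not given in the sources used here.

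Background was corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 under R 4.3.3, with control spots and outlier spots at weight 0. Spots marked as outliers by the scanner software (1877 over all arrays, 0.882% of study spots) were left out, and 1 saturated spot was kept. Ratios were taken as log2 of challenged over control, with the sign of swapped arrays turned. Spots of a probe were averaged, and the 2 arrays of a dye-swap pair were averaged to 1 replicate. A probe was tested where it was well above background on at least 6 of the 14 arrays in the challenged or in the control channel; 11185 probes were, and 11182 had enough values. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

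All 7 replicates entered 1 limma fit with a mean per time, so that both times shared their estimate of spread. Tested were the mean at 3 h, the mean at 12 h and the difference of 12 h and 3 h, with Benjamini-Hochberg adjustment over probes at 0.05. Pools are separate insects, so the p-values of this fit measure the spread between pools. Probes without a stated gene were named by ID under a rule fixed before the data were examined. Of probes past adjusted p 0.05 with the same sign in every replicate of that time, each sequence was represented by its brightest probe, and the 2 highest and the 2 lowest were named. Where fewer than 5 passed, the rule named the 10 with the smallest unadjusted p and said that they did not pass. Because no gene names were at hand, no more than 2 IDs that rose and 2 that fell are printed in all, those of the 12 h comparison, and their values are given for the other comparisons. Sets of probes and ID letter groups were chosen after the data were examined. Letter groups were tested for enrichment by Fisher's exact test (2-sided) over sequences, and by limma's camera and fry.

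The arrays lay on 2 slides, 6 arrays of 12 h replicates 1 to 3 on slide 1 and 8 arrays of all 3 h replicates and 12 h replicate 4 on slide 2. Slide was tested as a block and within the slide that held both times. The replicate numbers were checked for pairing. The deviations of same-numbered replicates from their group means correlated across probes at 0.57, 0.57 and 0.15 for numbers 1, 2 and 3, each above the 0.1 set in advance. The numbers were therefore treated as paired in a further fit of replicates 1 to 3 of both times, which leaves out 12 h replicate 4. The pairing comes from the values, not from the labels. Differently numbered replicates were not put through this check, so it cannot show that likeness goes by number. The ratios of 3 h replicates 1 and 2 correlated most with their own number at 12 h (0.56 and 0.17). Those of 3 h replicate 3 correlated more with 12 h replicate 1 (0.38) than with 12 h replicate 3 (0.30). Neither the check nor these correlations were repeated without the 145 probes whose ratios ranged over at least 6 log2 units between replicates. The median ratio of those probes was highest in replicate 1 and lowest in replicate 2 at both times, so the likeness may rest on them. Other background corrections, normalizations, filters, thresholds, dye orientations and left-out replicates were tried as alternatives.

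The median signal of study spots was 7.06 to 14.8 times the median background in Cy5 and 5.72 to 13.2 times in Cy3. Of the study's probes, 68.4% to 77.6% were well above background per channel and array. The number of arrays limits the precision. The steps were tested on simulated arrays in which 200 of 11182 probes changed with spread drawn independently per probe. Of probes changed 2-fold, 89.6% were recovered at 3 h, 97.0% at 12 h and 82.1% for the difference. Of those changed 1.41-fold, 58.2%, 62.7% and 37.3% were recovered. The changed probes were picked at random, and the median SE over tested probes was 0.075 at 3 h. NC_MG10054-1 and NC_OV7763-1, named below, had SEs of 0.27 and 0.38 at 3 h, so these shares do not hold for probes as variable as those. The simulation also left out the spread that real replicates share across probes. With 200 changed probes, 167 passed in the simulation at 3 h and 149 for the difference, where 0 passed in the real data. The Benjamini-Hochberg adjustment is stricter where fewer probes change. The shares can therefore overstate what would be found at 3 h and for the difference.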

Results

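Transcript levels in pools of 5 leafhopper females were compared between insects pricked with E. coli and insects pricked with sterilized water. The 14 arrays gave 3 biological replicates at 3 h and 4 at 12 h after pricking with about 1500 bacterial cells. Of 15133 probes, 11182 were tested, standing for 6395 sequences, and 68.4% to 77.6% of probes were well above background per channel and array. Values are log2 ratios of challenged over control pools. The arrays of a dye-swap pair correlated at 0.56 to 0.88 across probes once the sign was turned. Between replicates the ratios correlated across probes at 0.05 to 0.39 within 3 h and at -0.61 to 0.69 within 12 h, the lowest value being that of replicates 1 and 2. Probes are not independent replicates. The files do not pair the probe IDs with genes, so transcripts are given by ID.

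The 3 h comparison asked which transcripts differed early after the bacteria were introduced. The sequence with the smallest adjusted p rose at both of its probes. Its brighter probe, NC_MG10054-1, had a log2 ratio of 2.57 ± 0.26 (SD, n = 3), 5.92 times the control level, with replicates between 2.37 and 2.86. NC_OV7763-1 had a log2 ratio of 2.00 ± 0.64 (SD, n = 3) at 3 h, 4.00 times the control level. Neither passed (limma adjusted p = 0.096 and 0.34). In limma 0 probes passed adjusted p 0.05, and 611 had an unadjusted p under 0.05 where 559.1 are expected by chance. This unadjusted count was 424, 343 and 794 without 3 h replicate 1, 2 or 3. It was 638, 597, 578 and 799 without 12 h replicate 1, 2, 3 or 4. The excess was lost without 3 h replicate 1 or 2, but fewer replicates at 3 h also lower the power by themselves. With arrays centred on their median in place of loess 6 probes of 4 sequences passed, all higher and all among the probes higher at 12 h. With all 14 arrays, a dye effect and replicate as a random block 54 passed, 49 of them higher. That fit enters both arrays of a pool under 1 correlation for all probes (0.66). Where pools differ more than this, the swapped arrays count partly as extra replicates. Leaving out a replicate gave 2 probes without 3 h replicate 2, 1 without 12 h replicate 3 and 2 without 12 h replicate 4. NC_MG10054-1 passed under 4 of 23 alternatives, which were median centring, all 14 arrays, only the arrays with challenged RNA in Cy5, and leaving out 12 h replicate 4. NC_OV7763-1 passed with all 14 arrays.

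The 12 h comparison asked which transcripts differed later. Among probes past the threshold, with each sequence represented by its brightest probe, the largest rises were at NC_OV7763-1, with a log2 ratio of 3.72 ± 0.84 (SD, n = 4) or 13.1-fold (limma adjusted p = 0.0049), and at NC_MG10054-1, with 3.62 ± 0.67 (SD, n = 4) or 12.3-fold (limma adjusted p = 0.0035). The other probes of these sequences had 3.74 and 4.26. Under the same limits the largest falls were at NC_MYA4936-1, with -2.23 ± 0.35 (SD, n = 4; limma adjusted p = 0.0041), and at NC_EB1124-1, with -2.02 ± 0.62 (SD, n = 4; limma adjusted p = 0.0496). These 4 probes had the same sign in 4 of 4 replicates. NC_EB1124-1 passed under 7 of 25 alternatives only, and its other probe, at -1.61, did not pass (limma adjusted p = 0.061). Leaving out 3 h replicate 1 or 2 or any of the 4 replicates at 12 h ended its call, at values from -1.76 to -2.21. Without 12 h replicate 4 NC_OV7763-1 and NC_MYA4936-1 passed, at 4.06 and -2.37. With the same 3 replicates at 12 h fitted without the 3 h replicates, which then no longer shared in the spread, they did not pass at the same values.

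**Figure D1:**
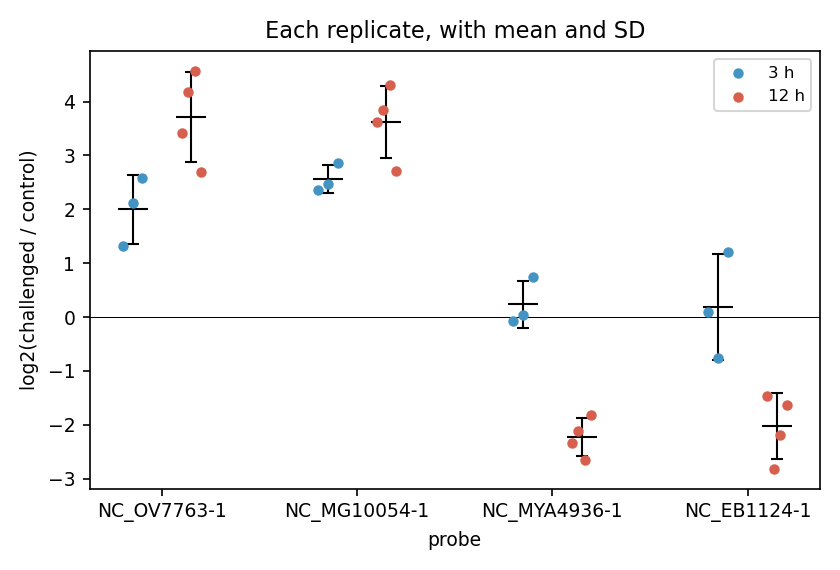
Log2 ratio of challenged over control pools (y axis) for 4 probes (x axis), with each point a biological replicate at 3 h (blue) or 12 h (red), and the bar and whiskers the mean and SD. At 12 h the points of NC_OV7763-1 and NC_MG10054-1 lie between 2.69 and 4.57, and those of NC_MYA4936-1 and NC_EB1124-1 between -2.82 and -1.46.

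In all, 123 probes passed at 12 h, 87 higher and 36 lower in challenged pools, standing for 58 and 30 sequences. At least 2-fold changes were found for 31 of the higher and 8 of the lower probes, and 9 probes of 5 sequences were at least 8-fold higher. Of 64 sequences with 2 tested probes and at least 1 past the threshold, both passed in 35 and the signs matched in 63. The excess of higher probes depended on how the dye swaps were used. With all 14 arrays, a dye effect and replicate as a random block 267 were higher and 257 lower. With only the arrays with challenged RNA in Cy5 the counts were 350 and 288, and with only those in Cy3 520 and 607. Dye effects do not cancel where only Cy5 or only Cy3 is used. With dye-swap pairs averaged and 1 replicate left out, the share of higher probes ran from 58.6% to 85.6%. It was lowest without 3 h replicate 3 (65 higher, 46 lower) and highest without 12 h replicate 2 (143 higher, 24 lower). Without 12 h replicate 3 there were 39 higher and 8 lower. The model and single replicates also moved the count. With slide as a random block 72 probes passed and with slide as a fixed term 61. The fixed term weighs 12 h replicate 4 as much as 12 h replicates 1 to 3 together. The 3 replicates of slide 1 at 12 h gave 106 with the 3 h replicates in the fit and 8 with the 3 h replicates left out. The count was 73 without 3 h replicate 1, 65 without 3 h replicate 2, 40 without 12 h replicate 1 and 47 without 12 h replicate 3. Without 12 h replicate 2, whose ratios ran against those of replicate 1, 167 probes passed, 83 of them among the 123. Of the probes that passed without 1 of the 12 h replicates, 38 of 40 had the same sign in the replicate left out for replicate 1, 98 of 167 for replicate 2, 46 of 47 for replicate 3, where the remaining probe had no value, and 92 of 106 for replicate 4.

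By ID letters, the higher probes were 17 MG, 16 Bac, 15 OV and 15 SGB, with the rest in 7 other groups. The lower probes held 15 Bac IDs, 0 MG and 0 SGB. Sequences with Bac IDs were enriched among the lower ones, 13 of 30 where 2.73 were expected (odds ratio 7.77, Fisher's exact test, 2-sided, adjusted p = 2.1e-05 over 28 tests). That test counts sequences read from the same pools as independent, so its p does not measure the spread between pools. Among the higher sequences 9 had Bac IDs where 5.29 were expected, and the Bac group as a whole did not shift at 12 h past the threshold (adjusted p = 0.74 in camera and 0.67 in fry, both of limma). This enrichment did not pass without 12 h replicate 1 (odds ratio 13.4) or 12 h replicate 3 (9.99), with slide as a fixed term (4.45), with the 3 replicates of slide 1 fitted without the 3 h replicates (9.97) or with only the arrays with challenged RNA in Cy5 (1.44). Its adjusted p ran from 8.6e-16 to 1 over the alternatives. It passed under 19 of 25, with odds ratios from 2.44 (only challenged RNA in Cy3) to 30.2 (each time fitted alone). Among these were 12.1, 13.4 and 20.7 without 3 h replicate 1, 2 or 3, and 3.69 with all 14 arrays. No letter group was enriched among the higher sequences, the smallest adjusted p being 0.42. In camera with a preset correlation the MG group lay above and the OV group below the other probes at 12 h (adjusted p = 0.034 for each), and with an estimated correlation neither passed (adjusted p = 0.81 for each). The MG group held 118 of 145 probes whose ratios ranged over at least 6 log2 units between replicates, with none of the 145 past the threshold at 12 h. Without these 145 probes 153 passed at 12 h, 100 higher and 53 lower.

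The comparison between times asked whether the response differed at 12 h from that at 3 h. NC_MYA4936-1 had a log2 ratio of 0.24 ± 0.44 (SD, n = 3) at 3 h, which became -0.01 without 3 h replicate 3, and its difference of 12 h minus 3 h was -2.47 ± 0.26 (SE). NC_EB1124-1 had 0.19 ± 0.99 (SD, n = 3) at 3 h, -0.33 without 3 h replicate 3, and differed by -2.21 ± 0.51 (SE). NC_OV7763-1 differed by 1.71 ± 0.50 (SE) and NC_MG10054-1 by 1.06 ± 0.36 (SE). None of these passed (limma adjusted p = 0.17, 0.33, 0.40 and 0.41). With all 14 arrays, a dye effect and replicate as a random block, NC_MYA4936-1, NC_EB1124-1 and NC_OV7763-1 passed. They were among 108 probes, 39 higher and 69 lower at 12 h than at 3 h. In that fit the swapped arrays of a pool can count partly as extra replicates. In limma 0 probes passed adjusted p 0.05, and 1325 had an unadjusted p under 0.05. With 1 replicate left out the unadjusted count ran from 744 (without 3 h replicate 1) to 1867 (without 12 h replicate 4). Without 3 h replicate 2 there were 2 and without 3 h replicate 3 there was 1, all lower at 12 h than at 3 h.

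With the replicate number as a block in a fit of replicates 1 to 3 of both times, which leaves out 12 h replicate 4, 6 probes of 5 sequences passed, all higher at 12 h than at 3 h. Without 12 h replicate 4 and with no block 0 passed in limma, and 1867 had an unadjusted p under 0.05. In both fits the 12 h replicates lay on slide 1 and the 3 h replicates on slide 2, so time and slide cannot be told apart there. With the block NC_OV7763-1 differed by 2.06 (limma adjusted p = 0.030; 0.030 to 0.98 over the alternatives), and NC_MYA4936-1, at -2.61, did not pass. The slide that held both times had 1 replicate of 12 h. Within it the difference was 0.69 for NC_OV7763-1, 0.15 for NC_MG10054-1, -2.05 for NC_MYA4936-1 and -1.81 for NC_EB1124-1. In limma 0 probes passed there and 710 had an unadjusted p under 0.05, but the spread came from the 3 h replicates alone and the lone 12 h replicate was assumed to vary like them, so the count says little. With slide as a fixed term 0 passed and 705 did so unadjusted. That fit also takes the difference from the lone 12 h replicate, with the same values for these probes, so it is no separate check.

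Because no probe passed at 3 h, 0 probes passed at both times and 0 were expected. Of the 87 probes higher at 12 h, 81 had a ratio above 0 at 3 h, with medians of 0.29, 0.24 and 0.30 in 3 h replicates 1, 2 and 3. As a set they were higher at 3 h in a test on the 3 h replicates alone (limma fry, adjusted p = 0.018 over 4 sets). Same-numbered replicates of both times deviated together across all tested probes, so the 3 h values cannot be taken as independent of how these probes were picked. Whether the 87 probes themselves deviated together was not tested. The 31 that rose at least 2-fold were all above 0 at 3 h, with a median log2 ratio of 1.21 at 3 h and 2.29 at 12 h. Of the 36 probes lower at 12 h, 18 had the same sign at 3 h (limma fry, adjusted p = 0.83), and of the 8 at least 2-fold lower 0 did. Over all tested probes the mean ratios of both times correlated across probes at Pearson r = 0.31 and Spearman rho = -0.05. Deviations shared by same-numbered replicates enter both means, so r does not measure a shared response alone. Single 3 h and 12 h replicates of the same number correlated at 0.56, 0.17 and 0.30, and those of other numbers at -0.62 to 0.44. Pearson r was 0.05 without 12 h replicate 1, 0.48 without 12 h replicate 2 and 0.21 without 12 h replicate 4. Spearman rho was 0.05 without 3 h replicate 1, and 0.02 without 12 h replicate 1 and without 12 h replicate 3.

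**Figure D2:**
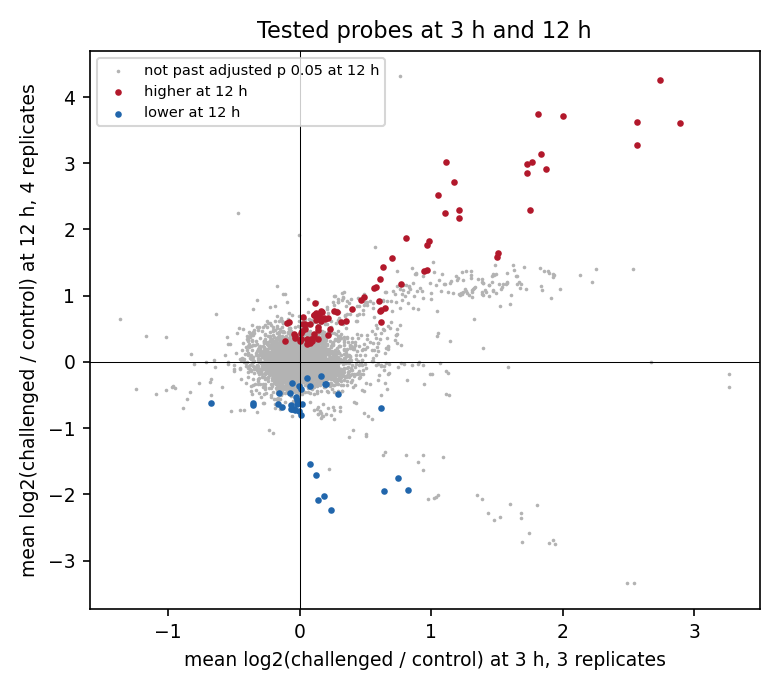
Mean log2 ratio of challenged over control at 3 h (x axis) and 12 h (y axis) for the 11182 tested probes, with those past adjusted p 0.05 at 12 h in red (87 higher) and blue (36 lower). Of the red points 81 lie right of 0, and of the blue points 18 lie left of 0.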

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

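The sets of probes described here, the tests of exchanged labels, of the challenge and of the slide, and the regroupings of the replicates were chosen or worded after the values were seen.

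A set of 19 probes (14 sequences; 10 probes with Bac and 5 with CE IDs) was higher in every 3 h replicate and lower in every 12 h replicate, with means of at least 2-fold at both times. Their median ratios were 3.22, 0.39 and 1.17 in 3 h replicates 1 to 3 and -1.76, -1.37, -2.81 and -3.59 in 12 h replicates 1 to 4. Control pools differed too, with median log2 levels of 10.04, 12.02 and 13.66 at 3 h and 12.83, 14.47, 14.68 and 15.04 at 12 h, against 13.29, 12.50 and 14.88 and 11.33, 13.15, 11.86 and 11.67 in challenged pools. The median difference of 12 h minus 3 h was -3.96, and within the slide holding both times -5.06. No probe of the 19 passed on its own in limma (smallest adjusted p = 0.27), and all 19 had an unadjusted p under 0.05. The difference of the set was not tested, since the set was picked for it. In the other direction 0 probes moved by as much.

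Of 25 sets of 12 h values examined for a replicate far from the others, 2 held one, where 1.25 are expected by chance. The median ratio of Bac probes was 0.030 in 12 h replicate 1, and that of MYA probes was -0.014 in 12 h replicate 4.

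In 12 h replicate 2 the ratios ran against those of 12 h replicate 1 (r = -0.61 across probes). An exchange of the challenged and control labels is argued against, since 100% of 14 probes at least 2-fold changed with one sign in every 3 h replicate kept that sign in 12 h replicate 2. A candidate source is a set of 145 probes whose ratios ranged over at least 6 log2 units between replicates, because without them r was 0.025. The set was picked for its range, with 124 of its probes lowest in 12 h replicate 2 and 125 highest in 12 h replicate 1, so leaving it out takes away extreme values whatever their origin. No biological explanation was tested.

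Of these 145 probes (93 sequences) 81.4% had MG IDs, against 9.83% of tested probes. Their median ratio was 3.20, 0.01 and 0.81 in 3 h replicates 1 to 3 and 4.11, -3.79, 1.90 and 2.24 in 12 h replicates 1 to 4, with median log2 levels in control pools from 7.35 to 12.10. The lowest ratio, -3.79, decides nothing about the challenge, since 0 tested probes had so wide a range with one sign and the choice of the set thus fixed that signs would differ. The spread left after probe and sample terms was 3.53 times that of other probes, over levels of at least 9 (log2), but this bound was unfit to judge a single source of RNA in a fixed ratio, since only 10 other probes had levels ranging as widely. Control pools, which were not challenged, differed among themselves at 12 h, with median log2 levels of 8.24, 12.10, 10.62 and 11.13 in replicates 1 to 4. Part of the range of these probes thus lay in unchallenged pools, which the challenge alone would not give. Control levels enter the ratios by which the set was picked, so the choice favoured such differences. The values therefore describe the picked probes only. A part played by the challenge, one or several sources of RNA, and a state of the insects that differed between pools all stay open.

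The 31 probes at least 2-fold higher at 12 h rose less in replicate 4, the only 12 h replicate on its slide. Their median there was 1.73, against 2.42 for the mean of the other medians. Most of them, 22 of the 31, were lowest in replicate 4, though not all. The 8 probes at least 2-fold lower showed no such loss, with -1.83 in replicate 4 and -1.49, -1.63 and -2.19 in replicates 1 to 3. Compressed ratios on that slide are argued against, since its slope of observed over expected spike-in ratios was 0.924 ± 0.0043 (SD, 8 arrays), 1.01 times that of the other slide. A difference between pools stays open and was not tested.

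Exchanging challenged and control within the 12 h replicates gives 8 arrangements, too few for a share under 0.05. The real one gave 123 probes and the highest other 104, so that only 1 of the 8, the real one, reached 123. Exchanging only 12 h replicate 2 gave 104 probes, 103 higher and 1 lower. The probes ranging over at least 6 log2 units had a median ratio of -3.79 in that replicate. In 12 h replicates 1, 3 and 4 their median was 4.11, 1.90 and 2.24. The exchange brings these medians to one sign, so 104 need not be a count reached by chance. How many of the 104 belong to that set was not tested. At 3 h there are 4 arrangements, too few as well, with 0 probes in the real one, 0 in the highest other and as many as the real one in 4. For the difference between times the real split gave 0 probes, so 35 of 35 splits of the replicates into 3 and 4 gave as many by construction and the comparison decides nothing; the highest other gave 0 as well.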

How the results depend on the processing

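Turning the sign of 12 h replicate 2 and leaving out the 145 pool-variable probes were chosen after the data were seen. The cause of a change was not tested, except that a stricter threshold lowers a count by construction. Signal over background limits small changes in dim probes. The gene list tests and the choice of 1 probe per gene were not run, since the files do not pair the IDs with genes.

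Probes passing at 3 h numbered 6 with median centring, 2 with scaled ratios, 1 with only probes above background in both channels on all arrays, 54 with all 14 arrays and a dye effect, 12 and 1 with only the arrays with challenged RNA in Cy5 or Cy3, and 1 without the pool-variable probes. At both times 6, 2, 1, 35, 12, 1 and 1 passed. The fit of all 14 arrays had replicate as a random block, and in it swapped arrays can count partly as extra replicates. Leaving out each replicate gave 0 to 2 at 3 h, 0 to 2 at both times and 0 to 2 for the difference between times, which gave 108 with all 14 arrays (39 higher, 69 lower) and 6 with the replicate block, which also leaves out 12 h replicate 4.

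At 12 h, 80 passed with the scanner's processed signals, 80 with the series matrix, 524 with all 14 arrays (267 higher, 257 lower), 638 (350, 288) and 1127 (520, 607) with Cy5 or Cy3 only, where dye effects do not cancel, 31 with each time fitted alone, 72 and 61 with slide as a random block or fixed term, 8 with the 3 replicates of slide 1 fitted without the 3 h replicates, 39 at 2-fold or more and 38 at adjusted p under 0.01. Leaving out each replicate gave 40 to 167. Pearson r of both times ran from 0.05 to 0.48 and Spearman rho from -0.13 to 0.05 when a replicate was left out.

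NC_MG10054-1 passed at 12 h under 24 of 25 alternatives, NC_OV7763-1 and NC_MYA4936-1 under 23 each and NC_EB1124-1 under 7. Directions turned at 3 h without 3 h replicate 3 for NC_MYA4936-1 (-0.014; 0.39 without 3 h replicate 1) and NC_EB1124-1 (-0.33; 0.66 without 3 h replicate 2). With 12 h replicate 2 turned they did so for the difference between times of NC_MG10054-1 (-0.86) and NC_OV7763-1 (-0.38). The odds ratio of the Bac enrichment was then 0 with 1 lower probe in all, which shows no direction.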

Other observations

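The counts here were chosen after the values were seen. Probes higher in all 7 replicates numbered 239, and those lower in all 7 numbered 162. Of those higher in all 7, 20 were at least 2-fold higher on average at both times, and of those lower 0 were. Probes higher in every 3 h and lower in every 12 h replicate numbered 202, and the reverse 164. Same-numbered replicates of both times deviated together, so no chance count is given.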
